A study of Mus musculus with 12 samples.

How the data were processed

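Gene expression was measured on 12 single-colour oligonucleotide arrays, 1 per RNA sample, from cultured mast cells of wild type (C57BL/6) and ACKR2-deficient mice at 2 and 10 weeks of culture, 3 arrays per group. Per the labels' protocols, marrow of the leg bones of female mice aged 4 to 6 weeks was grown with 12.5 ng/ml stem cell factor and 10 ng/ml interleukin 3, which drive marrow cells towards mast cells. Non-adherent cells were moved to new flasks after 48 hours and later about weekly, away from adherent fibroblasts. The protocols describe the mast cell population as homogeneous from 4 weeks on and state that, for some experiments, cells of 2-week cultures were enriched on a column for CD117, the stem cell factor receptor encoded by Kit. The labels do not say which arrays this concerns. From each sample, 250 ng of total RNA was made into biotinylated target with a whole-transcript kit. The labels call the 3 arrays of a group biological replicates and name no animal or culture for them.

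The deposited table holds 35399 probe sets on a log2 scale, made by the authors with RMA in Partek 6.5, per the submitters' processing notes. RMA corrects background, equalises the distributions of the arrays and summarises the probes of a probe set. Such values carry no detection call, and no scanner files were used here, so signal over background, slide and scan batches could not be examined. The values ran from 2.66 to 14.91, and the medians of the 12 arrays lay between 7.76 and 7.90, so the log2 scale was read from the values and the genes were not centred. The number of arrays, not a read depth, limits the precision. The genome build and annotation behind the probe sets are not given in the sources used here. A platform annotation paired 23410 probe sets with genes: 21789 had 1 gene symbol, 1621 had several and were not named, and 11989 were unnamed here. Symbols were used as the platform annotation gives them. Of their gene identifiers, 19856 were found in a RefSeq table of the mouse assembly GRCm38.p6, which served only to resolve older symbols and to find the neighbours of Ackr2. Where a gene had several probe sets, as 999 genes did, the probe set with the highest mean over all arrays was kept, which left 19938 genes. Genes of families with near-identical members, such as Cyp4a12a and Cyp4a12b, the Ifi200 genes, the mast cell proteases and the histones, can share probes, and their values are uncertain.

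A model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with 8 residual degrees of freedom and 2.39 prior degrees of freedom from the moderated variance. Contrasts were ACKR2-deficient against wild type at 2 weeks, at 10 weeks and on average, 10 against 2 weeks in each genotype, and the genotype by week interaction. P-values were adjusted with the Benjamini-Hochberg method over the 19938 genes of a contrast, and genes with an adjusted p under 0.05 were counted as changed. Errors of fold changes are limma's standard errors, and errors of group means are standard deviations over 3 arrays. All fold changes are differences of log2 values.

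Before the data were examined, 32 gene lists were written down, covering mast cell functions, other pathways, 11 other cell types of marrow cultures, and sex-linked genes as a check of the samples. Of their 599 different genes, 545 were measured, 1 of them found through an older symbol. Lists with at least 5 measured members, 31 in all, were tested with camera at a preset correlation of 0.01, adjusted over all 186 tests of 31 lists in 6 contrasts. Camera with a correlation estimated from the residuals and fry, a rotation test of a list on its own, were alternatives. Counts of members past the threshold were made over all genes and also adjusted over the list alone. Some genes stand in several lists. The genes named in the text follow a rule written at the same time. Per contrast these are Ackr2, the 8 genes with the largest positive and the 8 with the largest negative fold change among those past the threshold whose arrays do not overlap between the groups, and up to 4 changed members of a list that is described. Predicted genes, small RNAs, receptor gene segments and olfactory genes were left out of the ranked genes. Where no gene passed, the 5 genes with the lowest p and the 2 members of a list with the lowest p are given as values. Kit is named in addition because the protocols purify on its product, and this was decided after its values were seen.

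Whether the replicate numbers pair the arrays was checked from the correlation over genes of the deviations from the group means. Only between wild type at 2 and at 10 weeks did all 3 same-numbered pairs exceed 0.1, with correlations from 0.166 to 0.359, against at most 0.023 for pairs of different numbers. Such deviations depend strongly on any array apart from its group, so the check shows pairing neither present nor absent. With the replicate number as a block in the wild type arrays only, a fit added after the data were seen, limma called 0 genes in that contrast, with 1805 at an unadjusted p under 0.05. A block shared by all 4 groups also gave 0, with 1076.

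Other settings tried were fits to only the groups compared, trended and robust variances, genes above the median level (7.86, 10746 genes), a floor at the 20th percentile (6.14), cyclic loess, centring on medians, all probe sets, the mean of a gene's probe sets, array weights, the replicate block, a 2-fold minimum, and leaving out each array. Fits without the arrays in doubt were chosen after the data were seen. The steps were tested on simulated data drawn around the real means and residual spreads of the 19938 genes, with 200 genes changed in the ACKR2-deficient 10-week arrays. For the genotype contrast at 10 weeks with the spread of all 12 arrays, 59 of 100 genes with a 2-fold change and 91 of 100 with a 4-fold change were recovered, with 6 false calls. With the spread of the 10-week arrays alone, these were 53 and 93, with 16 false calls. For 10 against 2 weeks in ACKR2-deficient cells, 57 and 88 were recovered, with 10 false calls. Camera found the 1 simulated list of 30 genes shifted by 1 on the log2 scale and none of the other 30 lists. These simulated arrays have independent genes, unlike the real ones.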

Results

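The series holds expression values of bone marrow derived mast cells, cells grown from mouse marrow with stem cell factor and interleukin 3, from wild type mice and from mice without ACKR2, an atypical chemokine receptor that binds inflammatory CC chemokines and takes them up without the usual signalling. Cells were collected at 2 and at 10 weeks of culture, with 3 arrays per group and 12 in all. The design asks how gene expression differs between the genotypes at each time and between the times in each genotype. Values are log2 signals, and 19938 genes were tested. Because 4 arrays did not show the transcripts their labels call for, groups are named throughout as the arrays labelled with that genotype and time.

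Ackr2, the targeted gene, was not lower on the arrays labelled ACKR2-deficient. At 2 weeks its 1 probe set (10590427) read 8.19, 8.29 and 8.38 on the wild type arrays and 8.39, 7.79 and 9.43 on the ACKR2-deficient arrays, a difference of 0.25 ± 0.32 (SE) with a limma adjusted p of 0.764 after Benjamini-Hochberg adjustment. At 10 weeks it read 7.88, 8.26 and 8.35 against 8.35, 8.16 and 8.25, a difference of 0.08 ± 0.32 with a limma adjusted p of 0.999. The sign is not settled. Without ACKR2-deficient 2-week array 3 the first difference was -0.20, with array weights it was -0.16, and without wild type 10-week array 1 the second was -0.058. Which part of the gene was deleted and whether the probe set lies in it are not given in the sources used here. Its mean level was above that of 53.3% of genes, and whether it exceeds background on the wild type arrays could not be examined. For both reasons the probe set cannot be used to check the genotype.

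Mast cell transcripts were high on 8 arrays and low on 4. The 20 measured genes of mast cell receptors and identity averaged between 12 and 12.39 on the 6 arrays labelled 10 weeks and on wild type 2-week arrays 1 and 2. They averaged 7.49 on wild type 2-week array 3 and 7.48, 7.39 and 7.17 on the ACKR2-deficient 2-week arrays. Fcer1a, the alpha chain of the high-affinity IgE receptor, read between 4.83 and 5.47 on these 4 arrays and between 13.74 and 14.14 on the other 8. Kit, whose product was used for purification in some experiments, read 9.18, 9.16, 9.18 and 7.52 on the 4 arrays in the same order and at least 13.61 elsewhere. On the same 4 arrays B cell markers averaged 8.51, 8.69, 8.60 and 10.51, against 6.5 to 7 on the other 8, and MHC class II presentation genes averaged 11.37, 11.42, 11.45 and 12.40, against 7.43 to 9.57. T and NK cell markers averaged 11.10, 11.01, 11.04 and 8.58, against 6.78 to 7.49. ACKR2-deficient 2-week array 3 thus had the highest B cell and the lowest T and NK cell average of the 4. The labels give female mice for every array. Xist, the transcript of the inactive X chromosome, read between 5.77 and 6.23 on these 4 arrays and at least 13 on the other 8, while Kdm5d, a gene of the Y chromosome, read between 10.06 and 10.51 and at most 6.42. Over all genes, wild type 2-week array 3 was nearest to ACKR2-deficient 2-week array 2 (Pearson r = 0.997 across genes) and had r = 0.890 with array 1 of its own group. The first principal component, with 70.2% of the variance, separated these 4 arrays from the other 8.

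**Figure D1:**
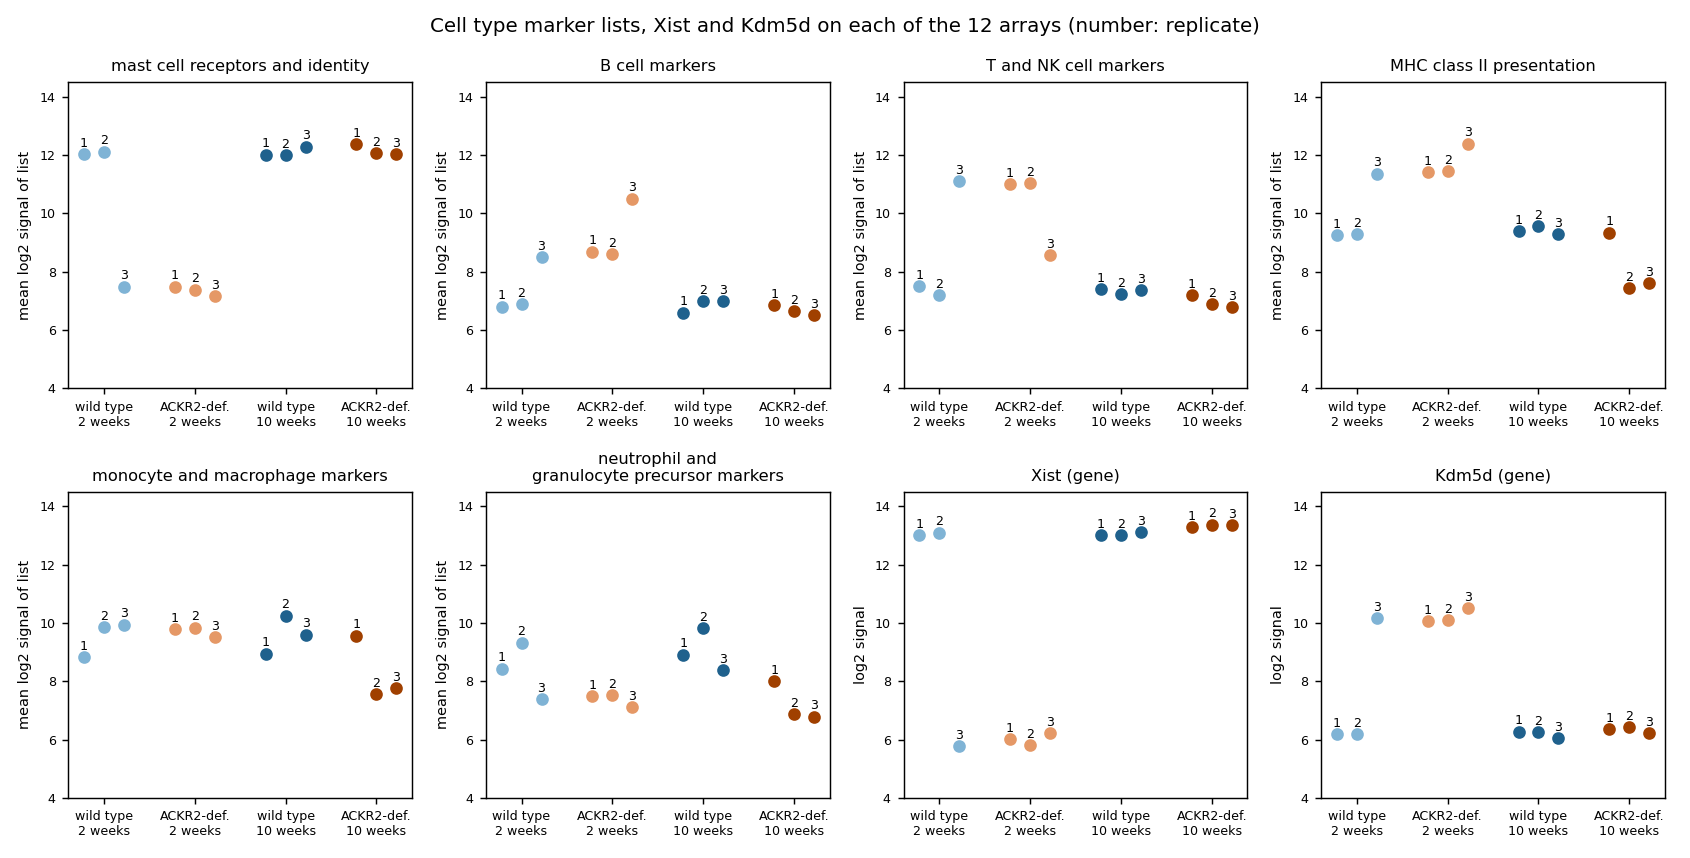
Mean log2 signal of 6 marker lists, and the log2 signal of Xist and Kdm5d, on each of the 12 arrays (vertical axes), by labelled group (horizontal axes), each point being 1 array numbered by its replicate. Wild type 2-week array 3 and the 3 ACKR2-deficient 2-week arrays lie between 7.17 and 7.49 for mast cell receptors and identity, and the other 8 lie at 12 or above.

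At 2 weeks, mast cell genes were lower and lymphocyte, MHC class II and interferon genes higher on average on the arrays labelled ACKR2-deficient, but 1 of the 3 wild type arrays had the levels of the ACKR2-deficient ones and no gene passed the threshold. Mast cell receptors and identity had a median log2 difference of -3.10 with 20 of 20 members below 0, and 19 passed when adjusted over the list alone. Cd63, a granule membrane protein, differed by -3.10 ± 0.81 and Mitf, a transcription factor of mast cells and melanocytes, by -2.27 ± 0.62. Of 11 B cell markers, 9 were above 0 and 7 passed when adjusted over the list alone, with Cd79a and Cd79b, parts of the B cell receptor, at 4.19 ± 1.11 and 2.44 ± 0.63. All 11 MHC class II presentation genes were above 0 (median 2.01) and 7 passed over the list alone, among them Ciita, the transcriptional activator of the class, at 2.12 ± 0.57. Interferon-stimulated genes had 24 of 25 members above 0 (median 0.80) and T and NK cell markers 12 of 13 (median 1.95), with Cd2 at 3.29 ± 1.13, and none of either list passed over the list alone. Cholesterol synthesis genes were below 0 in 17 of 17 cases (median -1.10, Sqle -1.98 ± 0.63), with none past the threshold over the list alone. Of the mast cell cytokines and growth factors, 13 of 25 passed over the list alone, all lower, including Osm at -2.37 ± 0.66. Camera placed 6 lists higher and 16 lower at the preset correlation, and with an estimated correlation their adjusted p lay between 0.439 and 0.607. Of these 22 calls 4 were lost without single arrays. Neutrophil markers lost it without wild type 2-week array 2 or 3, ACKR2-deficient 2-week array 3 or wild type 10-week array 1 (adjusted p between 0.0512 and 0.186). Erythroid markers lost it without wild type 2-week array 3 or ACKR2-deficient 2-week array 1 or 2 (0.104 to 0.176), the CC chemokines that ACKR2 binds without ACKR2-deficient 2-week array 3 (0.0907), and cell cycle genes without wild type 2-week array 1 (0.0569).

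For single genes at 2 weeks, limma called 0 of 19938 genes, with a lowest adjusted p of 0.140, while 3480 had an unadjusted p under 0.05 against 997 expected by chance. The lowest p values belonged to Synj2, an inositol phosphatase (-1.09 ± 0.13), to Ighg3 and Ighm, which encode immunoglobulin heavy chains (3.48 ± 0.61 and 2.74 ± 0.53), to Klrb1b, an NK cell receptor (0.89 ± 0.17), and to Alas2, of haem synthesis in red cell precursors (1.10 ± 0.21), none past the threshold. Without wild type 2-week array 3 limma called 4738 genes, without ACKR2-deficient 2-week array 3 it called 1, and with array weights 9197. The fit with 4738 genes sets 2 wild type arrays high in mast cell transcripts and Xist against 3 ACKR2-deficient arrays low in both. In it the genotype cannot be told apart from what else sets these arrays apart.

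At 10 weeks, mast cell receptor genes had a median log2 difference of 0.12 between the genotypes, while markers of neutrophils, eosinophils, monocytes and macrophages, MHC class II genes and granule proteases were lower on average on the arrays labelled ACKR2-deficient. The 19 neutrophil and granulocyte precursor markers were all below 0, with a median log2 difference of -2.12, and 8 fell when adjusted over the list alone. Lcn2, an iron-carrier-binding protein of neutrophil granules, differed by -2.93 ± 0.81, and Cebpe, a transcription factor of granulocyte maturation, by -0.62 ± 0.15. Of 8 eosinophil markers, 6 fell when adjusted over the list alone (median of all 8, -1.06), with Prg2 and Prg3, which encode granule major basic proteins, at -2.69 ± 0.72 and -1.36 ± 0.41. Monocyte and macrophage markers were below 0 in 20 of 21 cases (median -1.04), with Ms4a6c at -3.39 ± 0.88 and Adgre1, the F4/80 antigen, at -2.40 ± 0.75, and none passed over the list alone. MHC class II presentation genes had a median of -0.75 with Cd74, the invariant chain, at -3.42 ± 1.08, and mast cell granule proteases a median of -1.46 with Prss34, a basophil and mast cell protease, at -3.68 ± 1.35. Of the 11 CC chemokines that ACKR2 binds, 10 were below 0 (median -1.13). Ccl24, which attracts eosinophils, had the lowest p of them at -2.69 ± 0.62 and 1 member fell over the list alone. Immediate early and NF-kB response genes were below 0 in 27 of 30 cases (median -0.65), with Nr4a1 at -1.87 ± 0.49. Cell cycle genes were below 0 in 35 of 38 cases (median -0.32), with 1 past the threshold over the list alone and E2f2 at -1.14 ± 0.24. This rested on wild type 10-week array 1, where they averaged 10.62, against 9.76 and 8.95 on arrays 2 and 3 and 9.11, 9.60 and 9.63 on the ACKR2-deficient arrays, and without it their median was 0.10. By contrast, mast cell receptors and identity had a median of 0.12 with 14 of 20 members above 0 and none past the threshold, Hdc, the enzyme that makes histamine, having the lowest p at -1.45 ± 0.99. These errors include the spread of the wild type 2-week arrays, where the list averaged 12.05, 12.12 and 7.49. Such errors leave these genes little room to pass, so the lack of calls does not show equal levels. With only the groups compared, limma also called 0 genes at 10 weeks.

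The 3 arrays labelled ACKR2-deficient at 10 weeks differed among themselves in these lists. Monocyte and macrophage markers averaged 9.56 on array 1 and 7.56 and 7.77 on arrays 2 and 3, against 8.95 to 10.25 on wild type 10-week arrays. MHC class II presentation genes averaged 9.34, 7.43 and 7.60, against 9.29 to 9.57. Cd74 read 11.58, 6.70 and 6.84, against 11.65 to 12.06, and Prss34 read 11.30, 7.52 and 7.51, against 12.26 to 12.68. Neutrophil markers averaged 8.01, 6.86 and 6.78, against 8.37 to 9.83, so that all 3 arrays lay below the wild type arrays. Eosinophil markers averaged 7.63, 6.92 and 6.97, against 7.79 to 8.61, also below on all 3. The CC chemokines that ACKR2 binds were likewise below on all 3, at 8.965, 8.415 and 8.392, against 9.48 to 9.962.

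**Figure D2:**
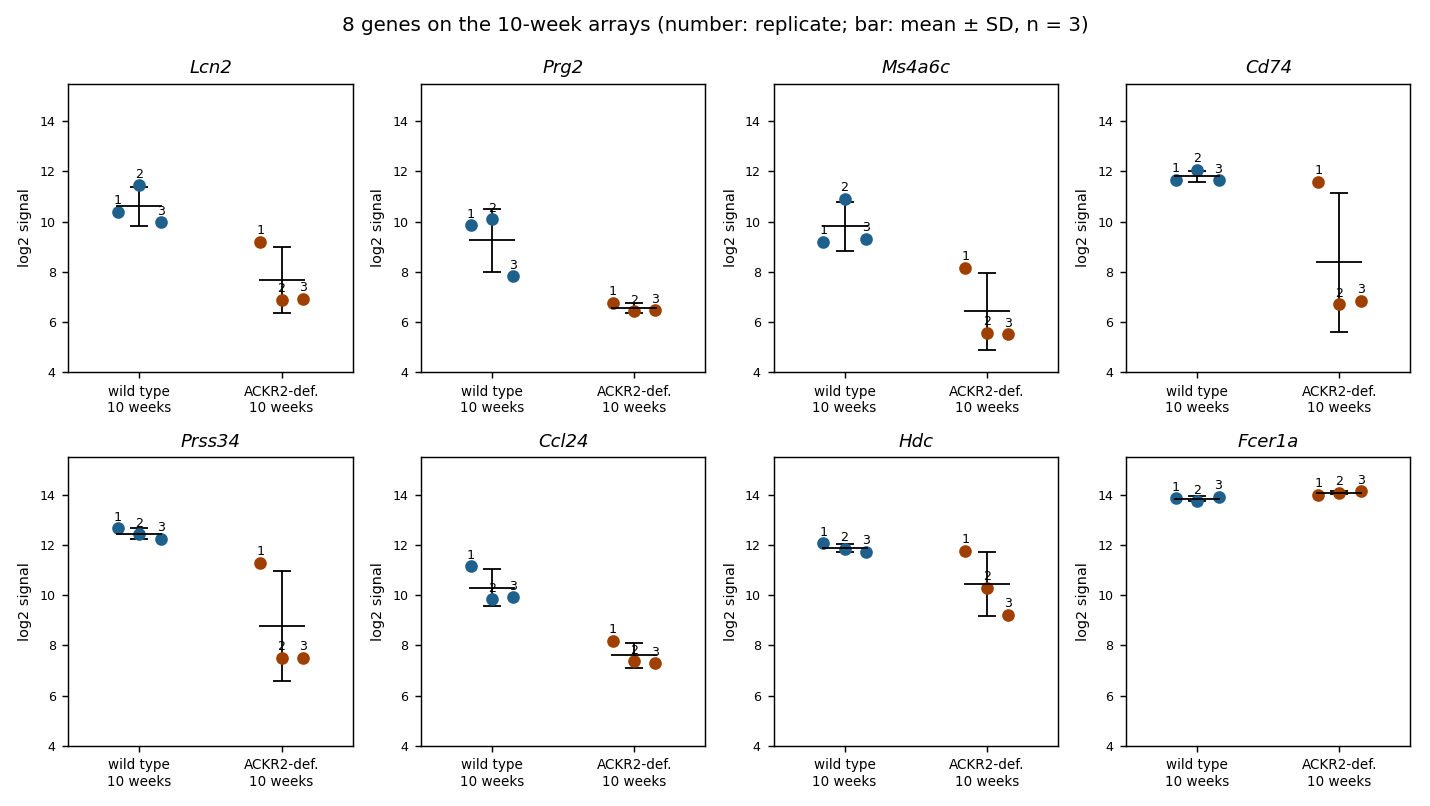
Log2 signal (vertical axes) of 8 genes on the 10-week arrays by labelled genotype (horizontal axes), with points for single arrays numbered by replicate and bars for the mean ± SD of 3 arrays. Cd74 and Prss34 are at 11.58 and 11.30 on ACKR2-deficient array 1 and at 7.52 or below on arrays 2 and 3, while Fcer1a lies between 13.74 and 14.14 on all 6 arrays.

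Limma called 0 of 19938 genes at 10 weeks after Benjamini-Hochberg adjustment, with a lowest adjusted p of 0.448 and 1566 genes at an unadjusted p under 0.05 against 997 expected by chance. The lowest p values belonged to Mmp14, a membrane-bound matrix protease (-0.68 ± 0.11), Pisd-ps2 (0.74 ± 0.12), Il1rap, a shared chain of interleukin 1 family receptors (0.65 ± 0.11), Tssc4 (-0.80 ± 0.13) and Marcksl1 (-1.30 ± 0.22), none past the threshold. Camera at the preset correlation placed 12 lists lower and 0 higher, with the neutrophil markers at an adjusted p of 5.42e-12, the monocyte and macrophage markers at 7.00e-08 and the CC chemokines that ACKR2 binds at 0.000248. With an estimated correlation the adjusted p of the 12 lists was between 0.439 and 0.667. Without wild type 10-week array 1 camera kept 7 of the 12 calls and added 1, stromal markers (adjusted p = 0.0324). The 5 lost were p53 targets (adjusted p = 0.731), cell cycle genes (0.362), basophil markers (0.0965), integrins and adhesion genes (0.0800) and granule proteases (0.0632), whose median was then -0.72. Without ACKR2-deficient 10-week array 1 camera gave adjusted p = 0.147 for cell cycle genes. Limma then called 129 genes, 96 of them lower, and when the other 10-week arrays were fitted alone, a choice made after seeing the data, it called 506, 406 of them lower. Array 1 correlated more with wild type 10-week arrays 2 and 3 (0.985 and 0.989) than with its own group (0.974 and 0.975). Leaving it out therefore favours more calls by its choice. In that last fit 12 of 30 immediate early and NF-kB response genes, 7 of 21 monocyte and macrophage markers and 7 of 15 granule proteases fell. The array left out was nearest to wild type in these lists, so these counts are no independent support. With an estimated correlation camera called 0 lists in that fit.

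Between 2 and 10 weeks in the arrays labelled ACKR2-deficient, 3358 genes changed, 2095 higher and 1263 lower at 10 weeks, and 2000 of them by at least 2-fold. The 2-week arrays of this contrast all had low Xist and high Y-linked genes, and the 10-week arrays the reverse. Time therefore cannot be told apart from what else sets these arrays apart. Below, rose and fell mean only higher and lower on the 10-week arrays. The 8 ranked genes with the largest increase included several of mast cells, and also Xist and 2 fatty acid hydroxylases. Fcer1a rose from 5.31 ± 0.14 to 14.08 ± 0.06 (SD, n = 3), a log2 fold change of 8.77 ± 1.87 with a limma adjusted p of 0.0148 after Benjamini-Hochberg adjustment. Ms4a2, the beta chain of the same receptor, rose by 7.56 ± 1.55, Cpa3, mast cell carboxypeptidase, by 7.81 ± 1.66, Tph1, which starts serotonin synthesis, by 7.46 ± 1.52, and Cyp11a1, which starts steroid synthesis, by 7.86 ± 1.69. Cyp4a12a and Cyp4a12b, fatty acid hydroxylases of near-identical sequence, rose by 7.89 ± 1.5 and 7.48 ± 1.42, and Xist by 7.32 ± 1.51. The genes with the largest decrease were Ifi209 (-6.85 ± 1.27), Ly86 (-6.54 ± 1.11), Ms4a4c (-6.45 ± 0.98), Slamf6, a lymphocyte surface receptor (-6.39 ± 1.30), the Y-linked Eif2s3y (-6.28 ± 1.32), Ifi214 (-6.12 ± 1.21), Ifi203 (-6.06 ± 1.08) and Jchain, the joining chain of secreted immunoglobulins (-6.06 ± 1.22). The limma adjusted p of these 16 genes lay between 0.0137 and 0.0150.

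By list, 18 of 20 mast cell receptor and identity genes rose and none fell (median 4.64), Cd200r3 by 6.72 ± 1.45. Among granule proteases 5 of 15 rose, including Gzmb by 5.67 ± 1.16, Cma1, a chymase, by 5.40 ± 1.11 and Tpsg1, a tryptase, by 5.23 ± 1.16, and 2 fell. Degranulation and lysosome genes rose in 15 of 21 cases and fell in 1, with Rab27b, a regulator of granule release, at 4.5 ± 1.00 and Cd63 at 4.45 ± 0.81. Of 15 eicosanoid synthesis genes 6 rose and none fell. They included Alox5 and Alox5ap of leukotriene synthesis (6.27 ± 1.29 and 3.07 ± 0.67) and Hpgds of prostaglandin D2 synthesis (2.63 ± 0.51). Of 25 mast cell cytokines and growth factors 12 rose, with Il6 at 6.46 ± 1.56, Lif at 4.23 ± 0.90 and Hgf at 4.06 ± 0.99. Among Fc epsilon receptor signalling genes 11 of 29 rose and 3 fell, with Gab2, an adaptor, at 3.20 ± 0.62. Granule proteoglycan and heparin synthesis genes rose in 9 of 20 cases and fell in 1, with Ndst2, a heparin sulfotransferase, at 2.97 ± 0.58. Cholesterol synthesis genes rose in 11 of 17 cases, Sqle by 2.80 ± 0.63 and Msmo1 by 2.51 ± 0.51, and 13 of 28 glycolysis and hypoxia genes rose, Ndrg1 by 3.09 ± 0.65, while Pdk1 fell by 3.20. Of 14 haematopoietic progenitor markers 8 rose and 1 fell, including Cd34 at 5.63 ± 1.32 and Meis1 at 4.15 ± 0.91, and of 9 megakaryocyte and platelet markers 4 rose, including Itga2b at 4.98 ± 0.93. No cell cycle gene of 38 passed the threshold, and E2f1 and E2f2 had the lowest p at 1.32 ± 0.46 and -0.77 ± 0.24. Adjusted over the list alone, the members that rose were 20 for mast cell receptors, 15 for degranulation, cholesterol synthesis and Fc epsilon receptor signalling, 14 for granule proteoglycan, 17 for glycolysis, 13 for cytokines, 8 for progenitors, 7 for eicosanoid synthesis, 5 for granule proteases, 4 for megakaryocytes and 0 for the cell cycle. At the same adjustment 3 members fell for granule proteoglycan, 3 for progenitors, 3 for Fc epsilon receptor signalling, 2 for cytokines, 2 for granule proteases and 1 each for eicosanoid synthesis, degranulation and glycolysis.

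Lists of lymphoid, dendritic, monocyte, MHC class II and interferon genes were mainly lower at 10 weeks. All 11 MHC class II presentation genes fell (median -3.85), H2-Aa by 5.70 and Cd74 by 5.32. Interferon-stimulated genes fell in 21 of 25 cases and rose in none (median -1.56), with Ifit3 at -4.35 ± 0.82 and Irf7, a regulator of interferon genes, at -2.73 ± 0.50. B cell markers fell in 7 of 11 cases, with Ms4a1 (CD20) at -5.66 ± 1.17 and Cd79a at -5.50 ± 1.11. Dendritic cell markers fell in 8 of 12 cases, with Irf8 at -3.80 ± 0.60 and Klrd1, also an NK cell receptor, at -5.34 ± 1.41. T and NK cell markers fell in 4 of 13 cases over all genes and 11 of 13 adjusted over the list alone, with Cd2 at -5.44 ± 1.13. Of 21 monocyte and macrophage markers 8 fell and 2 rose, with Ms4a6c at -4.67 ± 0.88, C1qc at -4.24 ± 0.96 and F13a1 at 4.45 ± 1.14. Immediate early and NF-kB response genes fell in 9 of 30 cases, Dusp2 by 3.28 and Zfp36 by 2.35, and 1 rose, Ier3 by 4.56 ± 0.86. Adjusted over the list alone, the members that fell were 11 for MHC class II, 21 for interferon, 7 for B cell, 10 for dendritic cell, 9 for monocyte and macrophage and 9 for immediate early genes, while 2 monocyte and macrophage markers and 1 immediate early gene rose.

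**Figure D3:**
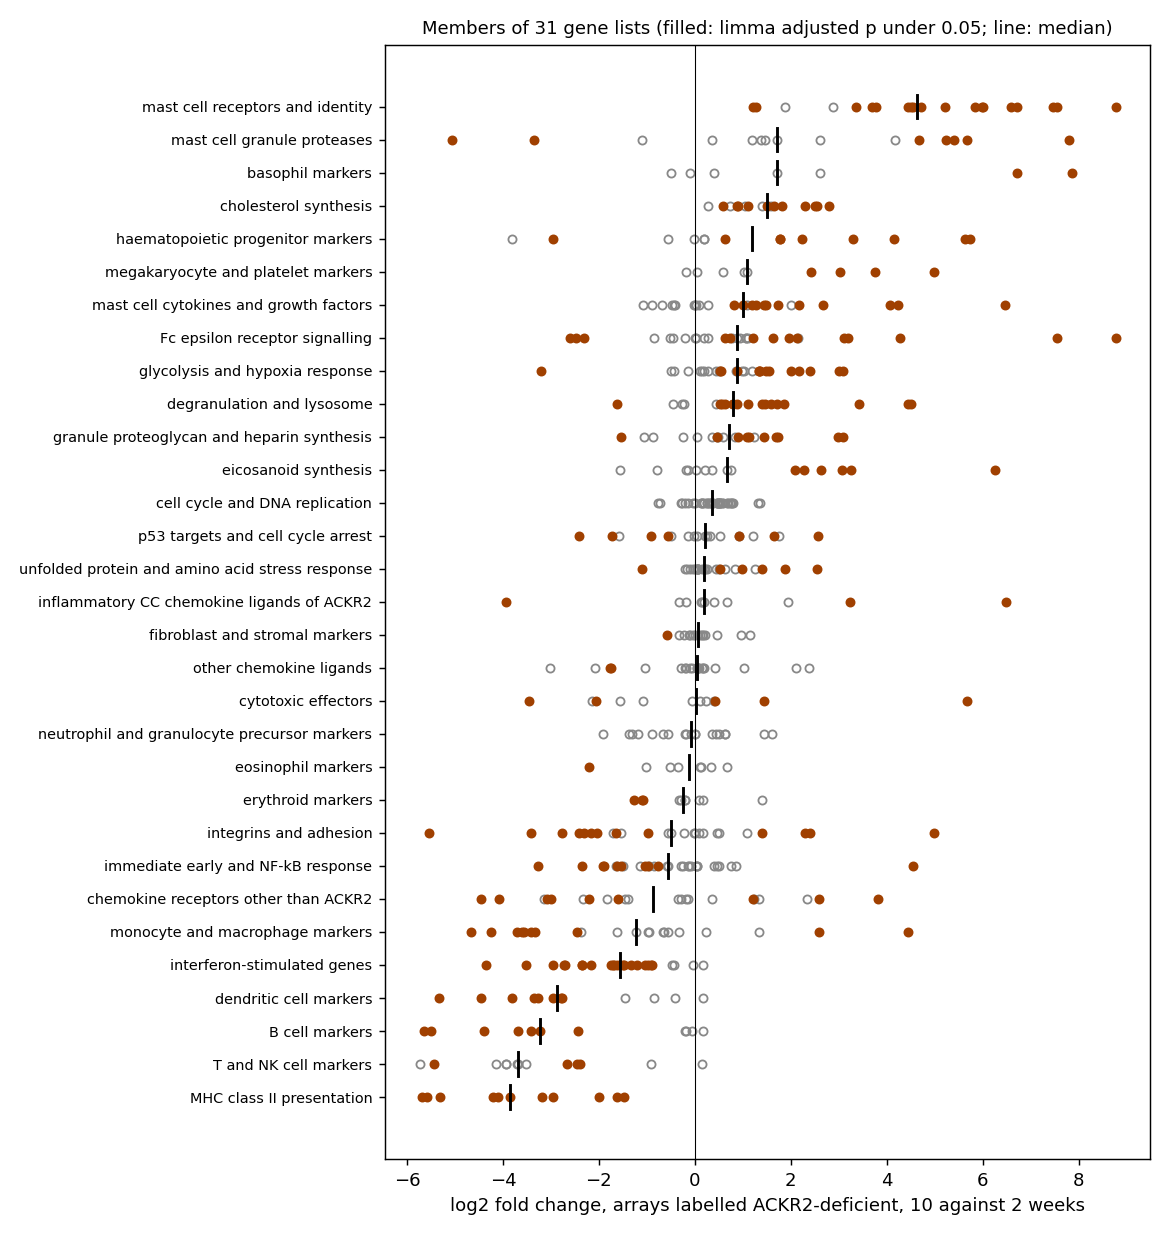
Log2 fold change of list members between 10 and 2 weeks on the arrays labelled ACKR2-deficient (horizontal axis, 3 arrays per time), by gene list (vertical axis). Filled points have a limma adjusted p under 0.05 and vertical lines mark list medians, which run from 4.64 for mast cell receptors and identity to -3.85 for MHC class II presentation.

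Camera at the preset correlation placed 10 lists higher and 10 lower at 10 weeks. With an estimated correlation all 20 lost the call, with adjusted p between 0.439 and 0.558. Each of these values sets the 3 arrays with low mast cell transcripts and high Y-linked signal against the 3 ACKR2-deficient 10-week arrays. The preset call of 5 lists was lost without single arrays. Eicosanoid synthesis, progenitor markers and cytokines lost it without ACKR2-deficient 2-week array 3 (adjusted p = 0.0715, 0.102 and 0.0502), eicosanoid synthesis and progenitor markers also without wild type 10-week array 1 (0.0576 each), and progenitor markers without ACKR2-deficient 10-week array 1 (0.0857). Erythroid markers lost it without wild type 2-week array 2 or 3 or ACKR2-deficient 2-week array 1 or 2 (0.0558, 0.0875, 0.158 and 0.106). Integrins and adhesion genes lost it without the same 4 arrays (0.0539, 0.111, 0.101 and 0.133), wild type 10-week array 1 (0.0604) and ACKR2-deficient 10-week array 2 or 3 (0.105 and 0.0845). Fry at its directional test called 0 lists and at its test of change in either direction 22. The count of genes was 0 without ACKR2-deficient 10-week array 2 and 0 without array 3, where the lowest limma adjusted p was 0.0555 and 0.0584 and 4783 and 4829 genes had an unadjusted p under 0.05. It was 1514 and 1391 without ACKR2-deficient 2-week array 1 or 2, and 9550 with array weights. The fits to all groups share 1 residual variance, which includes the distance of wild type 2-week array 3 from its group. Without that array limma called 4994 genes, and with only the groups compared 5003. Whether the counts of 0 would stay with only the groups compared was not tested.

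Between 2 and 10 weeks in the arrays labelled wild type, several of these lists differed on average and no gene passed the threshold, array 3 at 2 weeks having mast cell transcripts as low as the ACKR2-deficient 2-week arrays. Mast cell receptors and identity had a median of 1.36 with 20 of 20 members above 0, including Mrgprb2, a receptor for basic secretagogues, at 2.35 ± 1.20 and Il3ra at 0.65 ± 0.28. Interferon-stimulated genes were below 0 in 25 of 25 cases (median -0.62), with Ddx58 at -0.70 ± 0.20. Degranulation and lysosome genes had a median of 0.24 with 16 of 21 above 0, including Vamp8, of granule fusion, at 0.57 ± 0.16. Limma called 0 of 19938 genes, with a lowest adjusted p of 0.439 and 1326 genes at an unadjusted p under 0.05 against 997 expected by chance. The lowest p values belonged to Pdcd4 (-1.13 ± 0.16), Casp8, of the cell death pathway (-0.92 ± 0.14), Bin2 (-1.10 ± 0.18), Micos10 (0.83 ± 0.14) and Anapc13 (0.62 ± 0.11). Camera placed 6 lists higher and 4 lower, with adjusted p between 0.439 and 0.577 with an estimated correlation. With the replicate number as a block in the wild type arrays only, a fit chosen after seeing the data, it placed 9 higher and 5 lower, among them all 10, and with a block shared by all groups 8 higher and 5 lower. Without wild type 2-week array 3 all 10 calls were lost, the medians being -0.07 for mast cell receptors, -0.05 for interferon-stimulated and -0.06 for degranulation genes, and 1 other list, the cell cycle genes, was placed lower (median -0.35). Without wild type 10-week array 1 camera kept 4 of the 10. Neutrophil markers were also lost without wild type 2-week array 1 or 10-week array 2 (adjusted p = 0.126 and 0.471), MHC class II genes without wild type 10-week array 3 (0.0861), and megakaryocyte markers without wild type 10-week array 2 (0.262) or any 1 ACKR2-deficient 2-week array (0.0505 to 0.0621). In a fit chosen after seeing the data, without the 4 arrays low in mast cell transcripts, limma again called 0 genes, with 1424 at an unadjusted p under 0.05, and mast cell identity genes averaged 12.05 and 12.12 at 2 weeks against 12.02, 12 and 12.30 at 10 weeks. With wild type 2-week arrays 1 and 2 left out, limma called 2759 genes. The 2-week arm is then array 3 alone, 1 of the 4 arrays low in mast cell transcripts, assumed to vary like the other groups.

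Averaged over both times, limma called 0 genes between the genotypes, with 2589 at an unadjusted p under 0.05 and a lowest adjusted p of 0.350. Synj2 (-0.60 ± 0.09), H2bc18 (-0.49 ± 0.08), Mmp14 (-0.44 ± 0.08), Zfp866 (0.57 ± 0.11) and Nfil3, a transcription factor (-1.69 ± 0.32), had the lowest p, none past the threshold. Camera placed 3 lists higher and 21 lower, with the lowest p downward for the neutrophil markers (median -1.68) and mast cell receptors (median -1.53) and the most negative medians for basophil markers (-2.47) and granule proteases (-1.98), with adjusted p between 0.439 and 0.667 with an estimated correlation. Each of the 12 arrays, left out alone, ended 1 to 7 of these 24 calls, 9 different lists in all, with 7 lost without wild type 10-week array 1 and the highest adjusted p, 0.521, for monocyte and macrophage markers without wild type 2-week array 3. Fry's directional test called 0 lists. Its test of change in either direction called 3, the eosinophil markers (adjusted p = 0.0480), the CC chemokines that ACKR2 binds (0.0433) and the neutrophil markers (0.0470). The interaction of genotype and week had 0 genes past the limma threshold and 2271 at an unadjusted p under 0.05, with the lowest p for Mr1 (0.97 ± 0.17), Marcksl1 (-1.71 ± 0.31), Mei4 (-0.78 ± 0.14), Synj2 (0.99 ± 0.19) and Tent5a (1.56 ± 0.31). Without wild type 2-week array 3 these counts were 3543 and 3138, and with array weights 3720 and 4136. Without that array, high and low mast cell transcripts part the 2-week arrays as the genotype labels do, so the 2 cannot be told apart. Without ACKR2-deficient 10-week array 1 they were 53 and 29.

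No gene was called for genotype at both times. At an unadjusted p under 0.05 in both, 155 genes went the same way, against 133.6 expected for independent lists, and 57 went opposite ways, against 139.8. The fold changes of the genotypes at 2 and 10 weeks had a Pearson r of 0.002 across genes, which are not independent replicates. Because DNA of another strain can remain next to a targeted gene, the 115 measured genes within 10 Mb of it were compared with the other 19822. None was called for genotype by limma. At an unadjusted p under 0.05, 25.2% of the neighbours differed at 2 weeks against 17.4% of other genes (Fisher's exact test, two-sided, p = 0.0354), and 6.1% against 7.9% at 10 weeks (p = 0.602). The change from 2 to 10 weeks in the arrays labelled ACKR2-deficient, where both times share the genotype, gave 42.6% against 30.1% (Fisher's exact test, two-sided, p = 0.00567). Of the genes limma called for that change, 27 were among the 115 neighbours, 23.5% against 16.8% elsewhere (Fisher's exact test, two-sided, p = 0.0610). The share called for genotype in any of the 3 genotype contrasts was compared in 2 further fits, after seeing the data. Without wild type 2-week array 3, 45 neighbours were called, 39.1% against 25.7% of other genes (Fisher's exact test, two-sided, p = 0.00178), and with array weights 66, 57.4% against 47.1% (p = 0.0310). For genotype at 2 weeks alone these were 40 (34.8% against 23.7%) and 64 (55.7% against 46.1%), and neither fit called a gene at 10 weeks. The first fit sets 2-week arrays high in mast cell transcripts against arrays low in them. Neighbouring genes are also not independent, so these shares do not show DNA of another strain.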

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

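Apart from the splits of the samples, the tests of explanations in this part were chosen after the results had been seen. In 20 gene lists the difference between ACKR2-deficient and wild type arrays was not the same at 10 weeks as at 2 weeks, by camera on the genotype by week interaction at the preset correlation. With an estimated correlation none of the 20 passed, at adjusted p between 0.439 and 0.554. A positive median log2 value means that the ACKR2-deficient arrays stood higher relative to wild type at 10 weeks than at 2 weeks. The 9 positive medians were 3.35 for mast cell receptors and identity, 1.27 for cholesterol synthesis, 0.74 for Fc epsilon receptor signalling, 0.72 for eicosanoid synthesis, 0.62 for glycolysis and hypoxia response, 0.61 for degranulation and lysosome, 0.56 for megakaryocyte and platelet markers, 0.56 for mast cell cytokines and growth factors and 0.52 for granule proteoglycan and heparin synthesis. The 11 negative medians were -3.11 for MHC class II presentation, -2.52 for B cell markers, -2.10 for dendritic cell markers, -1.96 for T and NK cell markers, -1.59 for monocyte and macrophage markers, -0.98 for interferon-stimulated genes, -0.56 for neutrophil markers, -0.54 for eosinophil markers, -0.43 for immediate early and NF-kB response, -0.39 for chemokine receptors other than ACKR2 and -0.27 for erythroid markers. Each array other than wild type 2-week array 1, left out alone, ended the preset call of 1 to 6 lists, 10 different lists in all, with the most lost without ACKR2-deficient 2-week array 3 and the highest adjusted p, 0.404, for eosinophil markers without wild type 2-week array 3. In 15 of the 20 lists the mean of each of 4 arrays labelled 2 weeks, wild type array 3 and ACKR2-deficient arrays 1, 2 and 3, lay outside the range of the other 8, all 4 on the same side. The other 5, of monocyte, neutrophil, eosinophil, erythroid and immediate early genes, did not part these 4 arrays from the rest, and the monocyte, neutrophil, eosinophil and immediate early lists were lowest on ACKR2-deficient 10-week arrays 2 and 3. Limma called 0 single genes for the interaction, with 2271 at an unadjusted p under 0.05, and 3138 without wild type 2-week array 3 or 29 without ACKR2-deficient 10-week array 1.

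In the 15 lists that parted them, the differences moved with these 4 arrays, in which mast cell transcripts were low and B, T and NK cell transcripts high. Separate faults of single arrays are argued against as the cause for the 3 most alike of the 4 arrays. Their correlations over genes were at least 0.9964, against at most 0.8993 between any of the 4 and the other 8. The fourth, ACKR2-deficient 2-week array 3, had 0.964 to 0.9661 with them. A normalization or batch fault shared by the 4 arrays would also make them alike, so these values cannot decide on it. The array medians were 7.892 to 7.899 on the 4, against 7.762 to 7.832 on the other 8. An immature or mixed 2-week culture, the genotype and the week are each argued against as the cause as long as the mice were female as labelled, since Xist on the 4 arrays was at least 6.77 log2 units below the other 8, and 3 Y-linked genes were 3.64 to 5.97 above. A mislabelled sample, that is RNA from another source than the labelled cultures, remains a candidate explanation: all 4 of the 4 arrays had low Xist and high Y-linked genes. A wrong statement of sex together with a real difference between 2-week cultures stays open and untested, though genotype and week would not part wild type 2-week array 3, with a mean of 7.49 for mast cell receptors and identity, from arrays 1 and 2 of the same label, with 12.05 and 12.12.

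Other splits were drawn within weeks for the interaction, 100 of 200 possible, the real one included. The real count was 0, so that the other 99 were bound to give as many, which says nothing about chance. The highest other split gave 1929 genes. A split that calls so many genes points to a structure of the samples that the labels do not describe.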

How the results depend on the processing

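The fits with named arrays left out, other than each array in turn, and the block in wild type arrays only were chosen after seeing the data. With array weights, limma called 9197 genes for genotype at 2 weeks, 3720 on average and 4136 for the interaction, all 0 without weights, and 9550 for 10 against 2 weeks in ACKR2-deficient arrays (3358 without). It called 66 genes near Ackr2 (0 without), and the Ackr2 difference at 2 weeks became -0.16. The weights stopped before full convergence. A 2-fold minimum left 2000 of the 3358 genes. Leaving out wild type 2-week arrays 1 and 2, which leaves array 3 alone with the spread of the other groups, gave 2759 genes for 10 against 2 weeks in wild type and turned 2 values at 2 weeks, Cd2 to -0.31 and Tbx21 to -0.27. The 10-week arrays alone without ACKR2-deficient array 1 gave 506 genes for genotype at 10 weeks, and leaving out ACKR2-deficient 2-week array 3 and 10-week array 1 gave 1114 for 10 against 2 weeks. The cause of these changes was not tested.

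Leaving out each array in turn, counts ran from 0 to 4738 for genotype at 2 weeks, 0 to 129 at 10 weeks, 0 to 3543 on average, 0 to 3138 for the interaction, 0 to 45 for genes near Ackr2 and 0 to 4994 for 10 against 2 weeks in ACKR2-deficient arrays, with 0 throughout in wild type. The highest values came without wild type 2-week array 3, except 129, without ACKR2-deficient 10-week array 1. Without the former, the genotype labels at 2 weeks part the arrays as high and low mast cell transcripts do. The 0 of the ACKR2-deficient contrast came without 10-week array 2 or 3. The Ackr2 difference ran from -0.20 to 0.62 at 2 weeks and from -0.058 to 0.18 at 10 weeks, with adjusted p over all alternatives from 0.395 to 1 and from 0.890 to 1.

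In the ACKR2-deficient contrast, cyclic loess gave 3575 genes, of which 3203 were among the 3358, and centring on medians 3762, of which 3181 were. Centring moved the median of all genes from 0.06 to 0.16, and the share of higher calls from 62.4% to 71.1%. Of 110 named values past the threshold, 2067 of 2504 recomputed values kept direction and call, 437 lost the call and 0 reversed. Of 80 not past it, 1698 of 1825 stayed so, 125 passed and 2 reversed. Signal over background could not be examined from these values.

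With the replicate block shared by all groups, limma called 2897 genes for 10 against 2 weeks in ACKR2-deficient arrays, 2777 of them among the 3358, and 0 in the other contrasts. Camera then placed 11 lists higher and 8 lower there, against 10 and 10. Same-numbered pairs between groups other than wild type at both weeks correlated between -0.308 and 0.062. These values cannot exclude pairing, since deviations from a group mean depend strongly on any array that lies apart in its group. The wild type values do not settle it either. Those numbered 1 and 2 correlated at 0.359 and 0.203, against at most 0.023 for different numbers, so pairing of these stays open. The wild type arrays numbered 3 had a correlation of 0.166 although they differed in Xist and Y-linked signal. With the block in wild type arrays only, limma called 0 genes for 10 against 2 weeks in wild type.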

Other observations

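The tests of ACKR2-deficient 10-week array 1 were chosen after the result had been seen, that of fewer other cells being first run on 5 lists, all 5 lower, then widened to 11 and held to the spread of their members, and the splits of the samples before any split was computed. Several further lists had members that changed between 2 and 10 weeks in the arrays labelled ACKR2-deficient, in limma after Benjamini-Hochberg adjustment. Of 22 chemokine receptors other than ACKR2, 6 fell and 3 rose, and 7 and 3 adjusted over the list alone. Ccr7 and Cxcr5, which guide lymphocytes and dendritic cells in lymphoid tissue, were at -4.46 ± 0.80 and -4.08 ± 0.95, while Ackr1, another atypical chemokine receptor, rose by 3.82 ± 0.60 (camera adjusted p = 0.0113, and adjusted p = 0.439 with an estimated correlation). Of the 11 CC chemokines that ACKR2 binds, Ccl2 and Ccl7 rose by 6.49 ± 1.37 and 3.24 ± 0.95 and Ccl5 fell by 3.95, the same 2 and 1 adjusted over the list alone. Of 25 integrins and adhesion genes, 9 fell and 4 rose, Vcam1 by -5.55 ± 1.25 and Itgal, a leukocyte integrin chain, by -3.41 ± 0.67. Of 12 cytotoxic effectors 3 rose and 2 fell, the latter Nkg7 (-3.46 ± 0.82) and Gzma (-2.06 ± 0.52). Of 19 p53 targets 3 rose and 4 fell, with Phlda3 at 2.57 ± 0.54 and Btg2 at -2.42 ± 0.74. Of 26 unfolded protein and amino acid stress genes 5 rose and 1 fell, with Asns, which makes asparagine, at 2.55 ± 0.59 and Phgdh, which starts serine synthesis, at -1.09 ± 0.22. Of 10 erythroid markers 3 fell, among them Alas2 at -1.10 ± 0.21, and of 7 basophil markers 2 rose. In the lists of eosinophil, fibroblast and other chemokine genes 1, 1 and 2 fell, and none of 19 neutrophil markers passed. Adjusted over the list alone, 10 adhesion genes fell and 4 rose, 4 cytotoxic effectors fell and 3 rose, 6 p53 targets fell and 4 rose, and 5 stress genes rose and 1 fell. At the same adjustment 0 other chemokine genes fell, and 3 erythroid markers fell and 1 rose. These values set the 3 arrays with low mast cell transcripts and high Y-linked signal against the 10-week arrays, so time cannot be told apart from what else parts them. With the variance shared by all groups, 0 genes were called without ACKR2-deficient 10-week array 2 or 3. With only the groups compared and no array left out, 5003 were called.

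Cell cycle and DNA replication genes varied among arrays of the same label. Their mean was 10.56 and 10.62 on the arrays numbered 1 of wild type at 2 and 10 weeks, 9.70 and 9.76 on those numbered 2, and 9 and 8.95 on those numbered 3. On the ACKR2-deficient 10-week arrays it was 9.11, 9.60 and 9.63. The ACKR2-deficient 2-week arrays had 9.02, 9.03 and 9.27, near wild type 2-week array 3, which shared their low mast cell transcripts. The likeness of the wild type arrays numbered 3 therefore need not reflect the replicate number. Wild type 2-week array 1 was nearest to wild type 10-week array 1 (Pearson r = 0.993 across genes, which are not independent replicates). Wild type 10-week array 2 was nearest to wild type 2-week array 2 (0.9905), which was itself nearest to ACKR2-deficient 10-week array 1 (0.9906).

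ACKR2-deficient 10-week array 1 lay apart from arrays 2 and 3 of its group. The labelled genotype is shared by all 3 arrays, so it alone would not part them. The lower correlation of array 1 with wild type 10-week arrays 2 and 3 exceeded its higher correlation with its own group by 0.0093. This value restates that array 1 lay apart and is no separate test. Fewer cells of other types in the cultures of arrays 2 and 3 stays open. All 11 of 11 lists of other cell types had a median below 0 on arrays 2 and 3 minus array 1. The fall exceeded the spread of the members only for monocyte (-1.85) and B cell markers (-0.27), the other 9 lying within it. Basophil markers, among the 9, were lower in 7 of 7 cases (-1.12, spread 1.63). On array 1, B cell and stromal markers averaged only 6.86 and 7.48, and signal over background could not be examined. Such lists may have had little room to fall, so the spread cannot decide. MHC class II presentation genes, not among the 11, fell by more than their spread (-1, with 11 of 11 lower, spread 0.89). Mast cell receptors and identity had a median of 0. Mast cell granule proteases were also lower (-1.30, with 12 of 15 lower, within a spread of 2.52), some of which, such as Prss34, the basophil list shares. Immediate early genes were lower (-0.70, within a spread of 0.88), and cholesterol synthesis (0.86) and cell cycle genes (0.55) were higher. Whether fewer cells of other types would account for these lists was not tested. Whether array 1 is a wild type culture stays open, as no value decides it and the Ackr2 probe set, 0.14 apart from arrays 2 and 3, cannot check the genotype.

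With 3 arrays against 3, the 10 splits are too few for a share under 0.05. For 10 against 2 weeks in ACKR2-deficient arrays the real split gave 3358 genes and the highest other 4, so 1 of 10 gave as many. The real count was 0 for genotype at 2 weeks, genotype at 10 weeks and 10 against 2 weeks in wild type, so all 10 of 10 splits were bound to give as many in each, which says nothing about chance. The highest others were 1632, 0 and 22. The 1632 genes came from wild type 2-week arrays 1 and 2 with ACKR2-deficient 2-week array 3 against the rest, which points to a structure of the samples. For the average genotype difference, the real count was also 0, so that of 100 splits within weeks, the real one included, the other 99 were bound to give as many, which says nothing about chance. The highest other gave 1929, which points to the same structure.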
